A study of Ovis aries with 56 samples.

How the data were processed

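RNA of left and right amygdala of 30 sheep, in 15 pairs of same-sex twins of which 1 was treated, was hybridized to 2-colour Agilent arrays against pooled amygdala RNA, with dye swaps between arrays. The scanner signals were read with Agilent Feature Extraction 9.1, per the labels. The 56 deposited columns of values per sample are log2 ratios of the sample to the pool. The labels do not state the background correction, the normalization or the direction of these ratios, and medians of the 41 columns used lay between -0.02 and 0.02. For each group against the pool the authors also deposited log2 fold changes and a mean log2 brightness over all arrays. The deposited score is limma's moderated t of that fold change, as the authors computed it. The deposited p-values are those of that score, before and after the authors adjusted them for multiple testing. The signals of the single channels were not analysed here, so background and within-array normalization remain as the authors set them, and no spot can be called above or below background.

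Each array carries 10 spike-in probes with 20 spots each, added in known proportions to both channels. For each column the mean ratios of the spike-ins were set against the median of the other columns. In 15 columns the absolute slope was at most 0.208, the repeated spots of a spike-in had a mean SD of 0.697 to 1.12 and 27.4 to 40.9% of the probes had no value. These columns were left out by a slope minimum of 0.5. In the other 41 the absolute slope was 1.13 to 1.26, the SD 0.0760 to 0.194 and the share of probes without a value 2.49 to 19.6%. In 3 of the 41 (left and right replicate 6 of the male GnRHa group and female control right replicate 7) the slope was negative, with correlations of -0.995 for each. Their values were multiplied by -1 and their dye was taken as the opposite of the label. Left and right replicate 6 come from the same animal. A dye code, 0 for Cy3 and 1 for Cy5, was estimated for each array. Its departures from the Cy3 level fitted for its group were regressed on the dye differences of 500 probes. These came from a fit of the other unturned arrays of all groups. The 3 arrays had codes of 0.27, 0.91 and 0.92. Where the other arrays of a group held 1 dye, as for female control right replicate 7, the code rests on a comparison with those arrays. Of the 19 unturned arrays labelled Cy3, 18 lay nearer to Cy3, and of the 19 labelled Cy5, 18 lay nearer to Cy5. The design fixed before the data were examined used all 56 columns as labelled. The departure from it was made after the data were seen, so the planned count stands beside each count in the results.

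Control spots were left out and repeated spots of a probe averaged, which gave 15008 distinct probes. Of these 1414 had exactly 1 gene name, for 806 genes. Names came from accessions (524 probes), current symbols (456), old names (190), gene numbers (135), synonyms (37) and, for 72, the name in the files. The other 13594 probes had no gene name and are counted as unnamed. A probe was tested when it had at least 2 values in each of the 8 groups, which left 12930 probes and 716 named genes, with 9370 probes measured on all 41 arrays. Values were missing mainly in dim probes, with a mean log2 brightness of 5.37 to 5.39 against 6.22 to 6.40 for the values present.

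limma 3.58.1 in R 4.3.3 fitted 1 linear model to the 41 arrays with a mean for each of the 8 groups and the dye of the sample as a fixed term. Animal was a random block (duplicateCorrelation, within-animal correlation 0.147), and the moderated test came from eBayes, two-sided. p-values were adjusted by Benjamini and Hochberg over the probes of each comparison, with a threshold of 0.05. The 16 comparisons were the GnRHa effect in each sex, the sex difference without and with GnRHa, their interaction, right against left, the GnRHa effect and the sex difference within each side, and the GnRHa by side interaction in each sex. Differences are female minus male, GnRHa minus control and right minus left, and an interaction is the effect in females minus that in males or on the right minus that on the left. Values were read with numpy 2.4.6 and pandas in Python 3.11.15.

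Genes were named by a rule fixed before the data were examined, with 1 probe per gene, the brightest. It takes up to 10 increases and 10 decreases past the threshold in each of the 6 comparisons that average over sides or sexes, the 5 genes of lowest p where fewer than 5 pass, the 3 of lowest p in each comparison within a side, list members of lowest p, and 8 fixed receptor and enzyme genes. Not every gene that the rule takes is reported here. Of 30 gene lists written before the data were examined, 14 had at least 5 tested members. They were tested with limma's camera on the moderated statistics with a preset inter-gene correlation of 0.01, with p-values adjusted over the lists of a comparison. The same test with the estimated correlation and the rotation test fry were alternatives. Of the 6 calls in the 6 comparisons, 0 held with the estimated correlation. fry used the probes measured on every array, could test 5 of the 6, and called 0.

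Simulated data with the real design, missing values and spread were used to test the fit. Noise was drawn independently for each probe, with the within-animal correlation. Structure that many probes of an array share was not simulated, so false calls that come from it are not covered. Of 100 probes changed by 1 on the log2 scale 44 to 69% were called over the 6 comparisons, and of 100 changed by 0.5 between 7 and 30%. Of the calls 0 to 8.79% were unchanged probes, and the share was above 5% for GnRHa in females (5.83%), the treated sex difference (8.79%) and right against left (8.54%).

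Alternatives fixed before the data were examined were a filter on the dimmest 25% of the probes, no dye term, no block, the twin pair as random or as fixed replicate block, array weights, a variance prior with trend and robust estimation, the compared groups alone, and the mean of all probes of a gene. Alternatives added after the data were seen were all 56 columns as deposited, the 41 arrays as deposited, the 3 arrays left out, the 3 arrays turned with the dye as labelled, probes with a value on every array, a common scale between arrays, each array left out in turn, and the fit without 4 arrays that stood over 3 median absolute deviations from the median on the first principal component. The alternatives on background correction, on normalization within and between arrays and on the slide need signals of the single channels or a slide name and were not run. The counts of the 16 comparisons and of the gene lists were also set against splits of the samples that kept the group sizes, the real one included. The test of the sex difference between the sides was not. Sex was permuted among animals of 1 treatment, or the sides exchanged within animals, with 100 splits each. GnRHa and control were exchanged within twin pairs of the sex compared, which allows 16 splits in males and 8 in females, and for the interaction in both sexes (78 of 106 splits drawn).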

Results

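The arrays measured RNA of the amygdala, a forebrain region that takes part in emotional and social behaviour, in 50-week-old sheep. Treated animals had received implants of goserelin, an agonist of the gonadotropin-releasing hormone (GnRH) receptor whose continued presence lowers gonadotropin release. Per the labels, each implant held 3.6 mg and a new one was given at intervals of 4 weeks. Males began at an age of 8 weeks and females at 28, and the untreated twin of each treated animal served as its control. Each array compared 1 side of 1 animal's amygdala with a common pool of amygdala RNA, so every value is a log2 ratio to that pool. The 8 groups (male or female, control or GnRHa, left or right) held 7 arrays each. Of these 56 arrays, 15 were left out because the ratios of their added spike-in RNAs did not follow those of the other arrays, and 3 were turned because these ratios ran in the opposite direction. The 41 arrays used came from 25 animals. There were 5 of male control left, 4 of male control right, 6 of male GnRHa left, 6 of male GnRHa right and 5 of each of the 4 female groups. Their number limits the precision of every value. Differences are given as log2 difference ± standard error with limma's adjusted p, and group values as mean ± SD of arrays. A probe was called when its adjusted p was below 0.05.

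**Figure D1:**
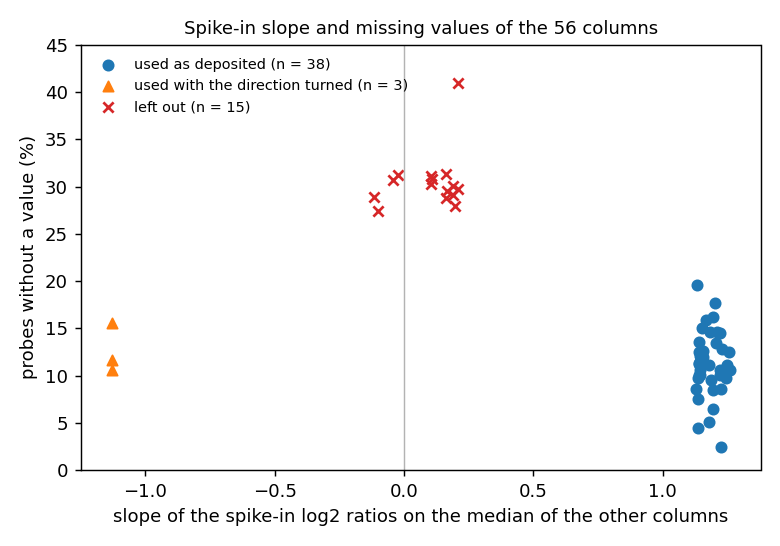
Each point is 1 of the 56 deposited columns, with the slope of its spike-in log2 ratios on the horizontal axis and the percentage of probes without a value on the vertical axis. The 15 columns left out have slopes between -0.12 and 0.21 and lack 27.4 to 40.9% of the probes, and the 3 turned arrays have slopes near -1.13.

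A pair of unnamed probes parted the sexes in every array that measured them. The probe for transcript FE028749 stood at -3.51 ± 0.76 in 16 female arrays and at 0.85 ± 0.27 in 21 male arrays. The probe for CU655072 stood at 0.56 ± 0.39 in 20 female arrays and at -1.24 ± 0.32 in 21 male arrays. With the 3 arrays turned, 0 arrays mismatched the sex of their labels on either probe. The pair had the lowest p for sex in both treatments. It was thus picked with these labels and turned arrays, and the absence of mismatches is no independent check of them. No probe with the name of a Y-linked gene or of XIST was on the array, so neither transcript is placed on a chromosome here.

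The sex difference in untreated animals was the comparison of 10 female with 9 male control arrays, averaged over the sides. It asks which genes are sex-biased in the amygdala without treatment. Of 12930 probes tested, limma called 134, with 90 higher and 44 lower in females. By their brightest probes, 6 named genes were higher and 4 lower in females, of 716 named genes tested. INHBA, which encodes a subunit of activins and inhibins, was lower in females by a log2 difference of -1.08 ± 0.25 (adjusted p = 0.0323). Its means were -0.77 ± 0.59 in 10 female and 0.35 ± 0.49 in 9 male arrays, and all 10 female arrays lay below the male mean. The other INHBA probe also passed, at a log2 difference of -1.10 (adjusted p = 0.0497). EDNRB, an endothelin receptor, was lower in females by -0.90 ± 0.19 (adjusted p = 0.0272; 10 of 10 female arrays below the male mean). The ribosomal protein gene RPS6 was lower by -0.38 ± 0.09 (adjusted p = 0.0363; 10 of 10), but by -0.06 (adjusted p = 0.942) with all 56 columns. ATXN2L, a relative of the ataxin-2 gene, was lower by -2.36 ± 0.51 (adjusted p = 0.0323; 8 of 8), but only 5 male arrays measured it.

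Of the genes higher in untreated females, HSPA1A, an inducible heat shock protein, differed most, by 0.94 ± 0.23 (adjusted p = 0.0371; 10 of 10 female arrays above the male mean). CXCL1, a chemokine that attracts neutrophils, was higher by 0.80 ± 0.20 (adjusted p = 0.0392; 10 of 10), and another CXCL1 probe was higher by 0.85 (adjusted p = 0.0272). TXNIP, which binds thioredoxin and responds to glucose, was higher by 0.65 ± 0.17 (adjusted p = 0.0492; 9 of 10). EEF1D, a translation elongation factor subunit, was higher by 0.57 ± 0.12 (adjusted p = 0.0272; 10 of 10). The glucose transporter SLC2A8 was higher by 0.56 ± 0.14 (adjusted p = 0.0473; 10 of 10), and the sterol reductase TM7SF2 by 0.48 ± 0.12 (adjusted p = 0.0453; 10 of 10). Of the 19 fits that left out 1 array, TXNIP stayed past the threshold in 5, SLC2A8 in 7, TM7SF2 in 8, HSPA1A and RPS6 in 9, CXCL1 and INHBA in 12, EEF1D and ATXN2L in 13 and EDNRB in 14. With all 56 columns none of these 10 genes passed.

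None of the 14 gene lists with at least 5 measured members shifted in this comparison. Among 6 stress and heat shock genes, 3 were higher and 3 lower, with 2 (HSPA1A and TXNIP) past the threshold over all probes and 5 adjusted over the list alone (adjusted p of the list 0.804). HSPA5, a chaperone of the endoplasmic reticulum, had a log2 difference of -0.47 ± 0.15 (adjusted p = 0.111). Of 11 genes of glutamate neurotransmission 7 were lower in females, with GRIA3 at -0.44 ± 0.16 (adjusted p = 0.169) and GRIA1 at -0.39 ± 0.15 (adjusted p = 0.195), both glutamate receptor subunits, and the list's adjusted p was 0.728. Of 12 genes of the GnRH and gonadotropin axis 7 were higher and 5 lower, and INHBA alone passed both thresholds (adjusted p of the list 0.944). All 6 microglia and macrophage genes were higher, with 0 past the threshold and a list adjusted p of 0.728. The number of calls rested on single arrays: it was 7 without male control right replicate 3 and 349 without male control left replicate 1. It was 2 with all 56 columns as planned before the data were examined, 13 without 4 arrays that stood far out on the first principal component, and 2 when the fit held these groups alone.

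**Figure D2:**
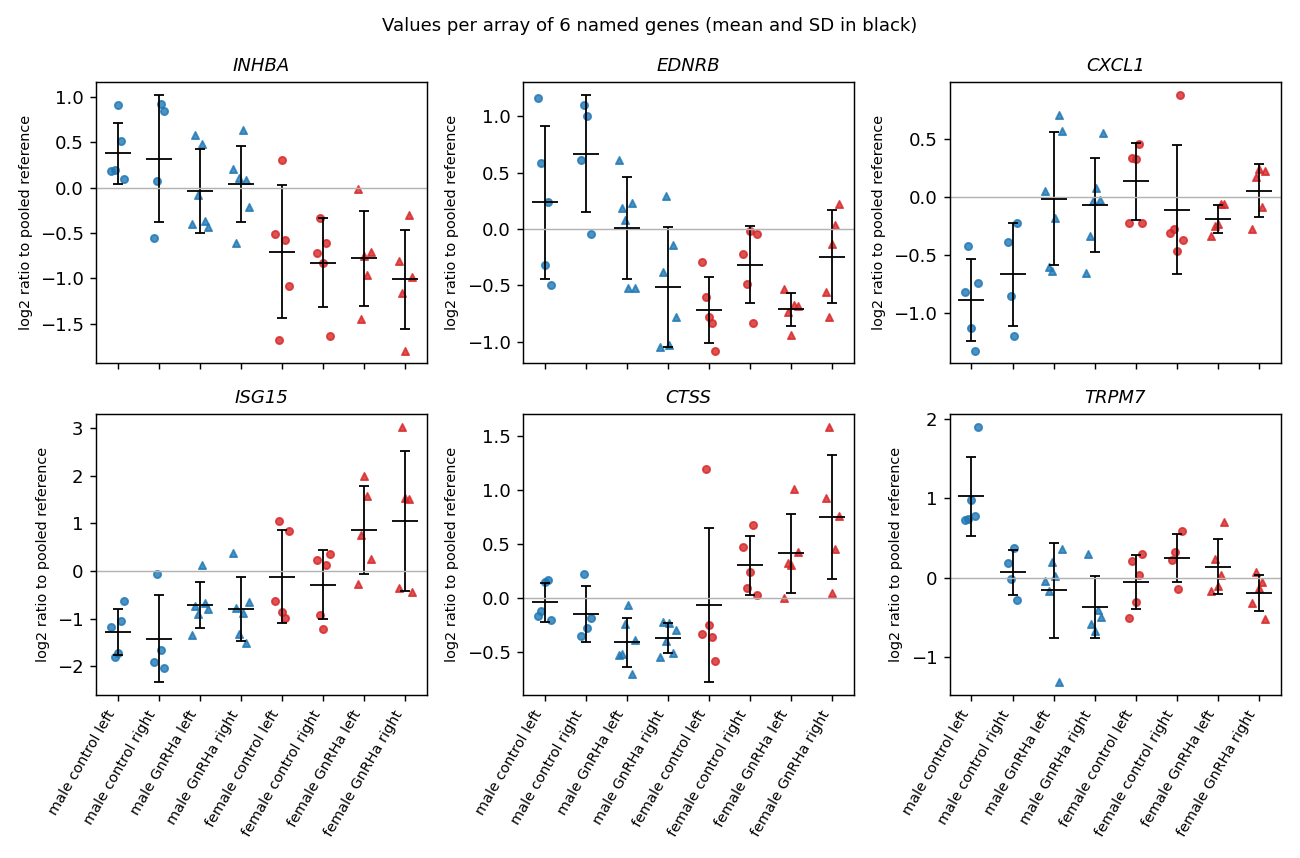
Log2 ratio to the pooled reference (vertical axis) of 6 named genes in each group (horizontal axis). Points are single arrays, circles for control and triangles for GnRHa, blue for males and red for females, and black bars give mean and SD. INHBA lies lower in females in every group pair, ISG15 and CTSS stand highest in GnRHa females, and TRPM7 stands highest in male control left.

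The sex difference in GnRHa-treated animals compared 10 female with 12 male GnRHa arrays and asks which sex biases are present under treatment. Since treatment began at different ages, sex and length of treatment go together in it. limma called 20 probes, with 19 higher and 1 lower in females. By their brightest probes 2 named genes were called, and a dimmer probe of CYBA also passed, as given below. CTSS, a lysosomal protease of microglia and antigen-presenting cells, was higher in females by 0.98 ± 0.18 (adjusted p = 0.0111). Its means were 0.58 ± 0.49 in 10 female and -0.39 ± 0.18 in 12 male arrays, and all 10 female arrays lay above the male mean. ISG15, a ubiquitin-like protein induced by interferon, was higher by 1.70 ± 0.38 (adjusted p = 0.0468; 10 of 10), with means of 0.96 ± 1.16 in females and -0.76 ± 0.55 in males. The 3 named genes next in order were CYBA, a subunit of the phagocyte NADPH oxidase, at 0.63 ± 0.15 (adjusted p = 0.0745; a dimmer CYBA probe passed at 0.66, adjusted p = 0.0433), NRP1, a semaphorin and VEGF co-receptor, at -0.76 ± 0.18 (adjusted p = 0.0749), and RTP4, which interferon induces, at 1.09 ± 0.26 (adjusted p = 0.0776).

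Both measured genes of antigen presentation had positive differences, CTSS as above and B2M at 0.86 ± 0.22 (adjusted p = 0.0930), and both passed adjusted over the list alone. Of the 4 interferon response genes measured, ISG15 passed both thresholds, IRF1 stood at 1.10 ± 0.47 (adjusted p = 0.562), MX1 at 0.47 ± 0.26 (adjusted p = 0.692) and MX2 at 0.17 ± 0.40 (adjusted p = 0.954). Among 6 microglia and macrophage genes 4 were higher and 2 lower, with CTSS past the threshold and FCER1G at 0.40 ± 0.13 (adjusted p = 0.303), and the list's adjusted p was 0.0677. The blood genes AHSP and HBB stood at -1.19 ± 0.48 (adjusted p = 0.512) and -0.01 ± 0.50 (adjusted p = 0.997). All 6 circadian clock genes were lower in females and the list passed the camera test with its preset correlation (adjusted p = 0.0323), with CRY1 at -0.56 ± 0.19 (adjusted p = 0.346) and PER1 at -0.83 ± 0.44 (adjusted p = 0.684). With an estimated correlation the list's adjusted p was 0.119. Ribosomal protein genes (15 of 18 higher, adjusted p = 0.0212) and astrocyte genes (4 of 5 higher, adjusted p = 0.0372) also passed with the preset correlation, and with an estimated correlation their adjusted p values were 0.341 and 0.280. The water channel AQP4 was the astrocyte gene of lowest p, at 0.42 ± 0.12 (adjusted p = 0.194). Of 11 genes of sex steroid receptors and steroid enzymes 9 were lower in females, with the oestrogen receptor ESR2 at -1.44 ± 0.47 (adjusted p = 0.319) and the cortisol-regenerating enzyme HSD11B1 at -0.62 ± 0.20 (adjusted p = 0.303), and the list's adjusted p was 0.0677. The count was 4 without male GnRHa left replicate 1 and 66 without female GnRHa right replicate 5, and ISG15 stayed past the threshold in 5 of the 22 fits that left out 1 array. It was 3 with all 56 columns as planned.

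Of the 134 probes called in untreated and the 20 called in treated animals, 2 were called in both, where 0.207 would be shared by independent lists. Those 2 were the sex-parting probes FE028749, with differences of -4.33 ± 0.26 untreated and -4.34 ± 0.25 treated, and CU655072, with 1.67 ± 0.16 and 1.91 ± 0.15. No named gene was called in both. Of the 134 probes, 104 had the same direction in treated animals, and their median difference was 0.66 untreated and 0.13 treated in the untreated direction. INHBA had a difference of -0.90 ± 0.24 in treated animals (adjusted p = 0.0980). Over all tested probes the direction was the same in 56.6%.

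The GnRHa effect in males compared 12 GnRHa with 9 control arrays. limma called 0 probes, with a lowest adjusted p of 0.0592, while 1519 had an unadjusted p under 0.05 where 646.5 would by chance. Named genes of low p are therefore given as values. TRPM7, an ion channel with a kinase domain, stood at -0.82 ± 0.19 (adjusted p = 0.0889; 11 of 11 GnRHa arrays below the control mean). CXCL1 stood at 0.73 ± 0.19 (adjusted p = 0.0956), with means of -0.04 ± 0.47 in 12 GnRHa and -0.79 ± 0.39 in 9 control arrays. The male control arrays behind this value are those behind its sex difference. ITGAV, an integrin subunit, stood at -0.66 ± 0.18 (adjusted p = 0.113) and EP4b, which 5 control arrays measured, at -1.84 ± 0.47 (adjusted p = 0.111).

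Of the genes fixed in advance, those given here did not pass in males. The oestrogen receptor ESR1 stood at 1.22 ± 0.65 (adjusted p = 0.471), the GnRH receptor GNRHR at 1.16 ± 0.67 (adjusted p = 0.529), the luteinizing hormone receptor LHCGR at 0.86 ± 0.50 (adjusted p = 0.53), the progesterone receptor PGR at 0.54 ± 0.57 (adjusted p = 0.761), the aromatase gene CYP19 at 0.28 ± 0.65 (adjusted p = 0.918) and ESR2 at 0.22 ± 0.55 (adjusted p = 0.925). KISS1R had no probe with its name. CYP19, ESR2 and PGR were dim, with a mean log2 brightness of 5.22, 5.28 and 5.37. Probes without a value averaged 5.37 to 5.39 on the 41 arrays. GNRHR was measured on 6 GnRHa and 4 control arrays of males and CYP19 on 6 and 5. That these genes did not pass therefore does not show that they were unchanged. Of 18 ribosomal protein genes 14 were lower with GnRHa, and the list fell by a mean of 0.13 on the log2 scale in the camera test with its preset correlation (adjusted p = 0.0360), with RPL14 at -0.33 ± 0.10 (adjusted p = 0.150) past the threshold adjusted over the list alone. With an estimated correlation the list's adjusted p was 0.810. Of 14 genes of the growth hormone and IGF axis 10 were higher (adjusted p of the list 0.321), with IGFBP3 at 0.36 ± 0.18 (adjusted p = 0.422). Of 6 microglia and macrophage genes 3 were higher and 3 lower (adjusted p of the list 0.806). TYROBP at 0.26 ± 0.08 (adjusted p = 0.172) and ITGAM at 1.49 ± 0.54 (adjusted p = 0.264) passed adjusted over the list alone, and the list's median was negative while its mean was positive. Since treated and control animals are twins, the pair was also a block, and the count was 62 with it as a random and 0 with it as a fixed block. Without male control right replicate 5 the count was 136, with array weights 178, and with all 56 columns as planned 0.

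The GnRHa effect in females compared 10 GnRHa with 10 control arrays. limma called 0 probes, with a lowest adjusted p of 0.156, and 480 had an unadjusted p under 0.05 where 646.5 would by chance. PYGL, the liver form of glycogen phosphorylase, stood at -0.53 ± 0.16 (adjusted p = 0.647; 10 of 10 GnRHa arrays below the control mean). TNFSF13B, a survival factor of B cells, stood at 1.46 ± 0.43 (adjusted p = 0.704), ISG15 at 1.18 ± 0.39 (adjusted p = 0.894), the protease gene CAPN3 at 0.47 ± 0.16 (adjusted p = 0.932) and PAG6, a pregnancy-associated glycoprotein, at -1.44 ± 0.46 (adjusted p = 0.944). Of the interferon response genes ISG15 and MX1 (0.67 ± 0.27), and of the antigen presentation genes B2M (0.64 ± 0.23) and CTSS (0.47 ± 0.18), passed adjusted over the list alone and not over all probes. ESR1 stood at 1.14 ± 0.66, GNRHR at -0.72 ± 0.60, CYP19 at 0.39 ± 0.66, PGR at -0.26 ± 0.58, ESR2 at -0.23 ± 0.52 and LHCGR at -0.11 ± 0.55, each with an adjusted p that rounds to 1. GNRHR was measured on 6 GnRHa and 7 control arrays of females and CYP19 on 6 and 6, so their values are imprecise. No list shifted. The lowest of their adjusted p values was 0.854, which many lists shared, and of these the microglia and macrophage genes had the lowest unadjusted p (0.0658; 3 of 6 higher). The count was 1 with the twin pair as a random and 0 with it as a fixed block, 0 with all 56 columns as planned and 3 without female control left replicate 4.

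The sex by GnRHa interaction tests whether the GnRHa effect differed between females and males. Since treatment began at different ages, sex and length of treatment go together here too. limma called 0 probes, with a lowest adjusted p of 0.413, and 996 had an unadjusted p under 0.05. MTHFD2, a mitochondrial folate enzyme, stood at -2.58 ± 0.73 (adjusted p = 0.459), TNFSF13B at 2.08 ± 0.63 (adjusted p = 0.470), TGFB2 at 0.76 ± 0.25, RPS6 at 0.38 ± 0.12 and EEF1D at -0.51 ± 0.17 (adjusted p = 0.480 for each of the last 3). GNRHR stood at -1.89 ± 0.90 (adjusted p = 0.652), LHCGR at -0.96 ± 0.74, PGR at -0.80 ± 0.82, ESR2 at -0.45 ± 0.76, CYP19 at 0.11 ± 0.93 and ESR1 at -0.08 ± 0.93. As above, CYP19, ESR2 and PGR were dim, and GNRHR and CYP19 were measured on few arrays. Of 18 ribosomal protein genes 14 had a positive interaction and the list passed with the preset correlation (adjusted p = 0.0293), with RPL14 at 0.35 ± 0.14 (adjusted p = 0.553). With an estimated correlation its adjusted p was 0.809. In simulated data of the same design 44% of probes that changed by 1 on the log2 scale and 7% of those that changed by 0.5 were called, so smaller interactions would seldom be called with these arrays. With all 56 columns as planned the count was 0.

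Right against left amygdala compared 20 right with 21 left arrays of all animals. limma called 29 probes, 16 higher and 13 lower on the right, with the dye as a term in the model. PLIN5, a coat protein of lipid droplets, had a fitted difference of 1.02 ± 0.20 (adjusted p = 0.0221), and its means were 0.15 ± 0.56 on the right and 0.03 ± 0.55 on the left. TNNC2, a troponin of fast skeletal muscle, had a fitted difference of 1.41 ± 0.29 (adjusted p = 0.0300), with means of 0.42 ± 0.60 and 0.20 ± 0.85. Without a dye term PLIN5 stood at 0.13 (adjusted p = 0.749) and TNNC2 at 0.24 (adjusted p = 0.643). PADI3, an enzyme that converts protein arginine to citrulline, had a fitted difference of -2.23 ± 0.43 (adjusted p = 0.0300), although its right mean of 0.64 ± 1.14 lay above its left mean of 0.17 ± 1.17. Its direction therefore came from the dye term. The cytokine gene IL6 stood at -2.19 ± 0.46 (adjusted p = 0.0659) and the transcription factor gene ARNT2 at -1.24 ± 0.31 (adjusted p = 0.0844). Of 18 ribosomal protein genes 16 were higher on the right (adjusted p = 0.00194 with the preset correlation), with RPS6 at 0.30 ± 0.09 (adjusted p = 0.163). With an estimated correlation the list's adjusted p was 0.881. The pituitary transcription factor gene POU1F1, at 2.07 ± 0.52 (adjusted p = 0.112), passed adjusted over its list alone, and the list of hypothalamus and pituitary genes had an adjusted p of 0.738. As fitted, all left female arrays carried Cy3 and all right ones Cy5 (1 of these, a turned array, is labelled Cy3), so in females the fit cannot separate side and dye. The count was 557 without a dye term, 3 with the dye of the turned arrays as labelled, 0 with all 56 columns as planned, 11 with the twin pair as a replicate block and 3 without male GnRHa right replicate 2.

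Within each side, the sex difference in the untreated left amygdala gave 661 called probes (334 higher and 327 lower in females; 5 female and 5 male arrays) and that in the untreated right amygdala 10 (2 higher and 8 lower; 5 and 4 arrays). On the left, EEF1D was higher in females by 0.84 ± 0.16 (adjusted p = 0.00708), and ACVR2A, a receptor of activins, was lower by -1.06 ± 0.24 (adjusted p = 0.0135), as was ITGAV by -1.08 ± 0.25 (adjusted p = 0.0135). On the right, HRH2, a histamine receptor, stood at -0.57 ± 0.13, the cytokine gene MIF at -0.68 ± 0.17 (adjusted p = 0.0954 for both) and ATXN2L at -3.06 ± 0.71 (adjusted p = 0.10). A test of the difference between the sides itself, run in the main fit alone, called 136 probes, 80 of them among the 661. Of the 661 probes, 383 had the same direction on the right, and their median difference was 0.78 on the left and 0.05 on the right in the left direction. With 1 array left out, the left count ran from 128 without male control left replicate 3 to 921 without male control left replicate 1. The right count ran from 3 without female control right replicate 1 to 52 without female control right replicate 4. Left and right counts were 25 and 13 without the 4 arrays far out on the first principal component (2 of them female control left), 3 and 1 with the compared groups alone in the fit, 402 and 181 with array weights, and 3 and 0 with all 56 columns.

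**Figure D3:**
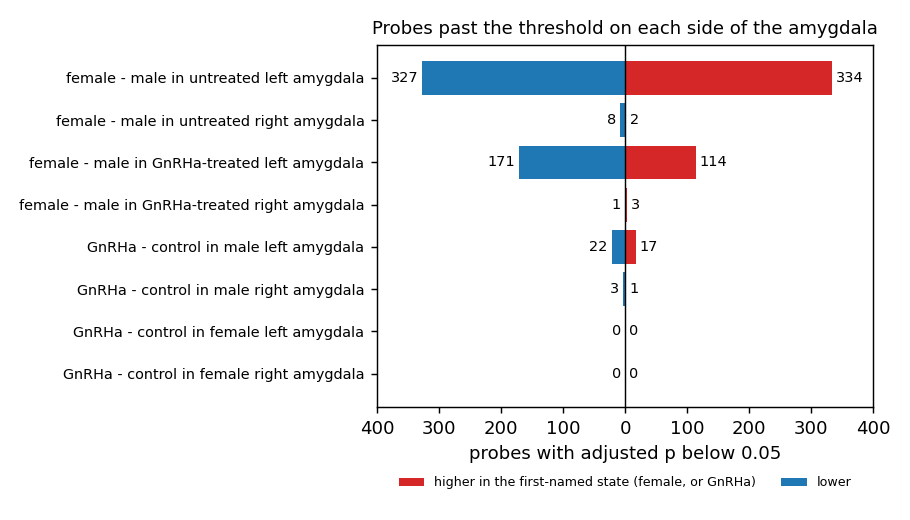
Bars give the number of probes with adjusted p below 0.05 (horizontal axis) in each comparison within a side (vertical axis), red for higher and blue for lower in females or with GnRHa. The untreated left amygdala has 334 probes higher and 327 lower in females, against 2 and 8 on the right.

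In GnRHa-treated animals the sex difference gave 285 probes on the left (114 higher and 171 lower in females; 5 and 6 arrays) and 4 on the right (3 higher and 1 lower; 5 and 6 arrays). On the left NRP1 was lower in females by -1.08 ± 0.25, the clock gene CRY1 by -1.12 ± 0.26 and HSD11B1 by -1.12 ± 0.28 (adjusted p = 0.0320 for each). Of the 11 fits that left out 1 array, NRP1 and CRY1 passed in 6 and HSD11B1 in 4, and over the settings HSD11B1 ran from -1.18 to -0.37 and CRY1 from -1.27 to -0.53. On the right CTSS stood at 1.15 ± 0.24 (adjusted p = 0.0561), RTP4 at 1.71 ± 0.36 (adjusted p = 0.0597) and the amino acid transporter gene SLC7A5 at -1.64 ± 0.37 (adjusted p = 0.0643). Of the 661 probes called on the untreated left, 10 were among the 285, where independent lists would share 14.6, and 513 had the same direction there. The left count was 16 without female GnRHa left replicate 6 and 582 without female GnRHa left replicate 5, and the right count 22 without female GnRHa right replicate 5. With all 56 columns the counts were 8 and 0, with the compared groups alone in the fit 8 and 3, and with array weights 2556 and 59.

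The GnRHa effect gave 39 probes in the male left amygdala (17 higher and 22 lower with GnRHa; 6 GnRHa and 5 control arrays) and 4 in the male right (1 higher and 3 lower; 6 and 4 arrays). TRPM7 was lower with GnRHa on the left by -1.13 ± 0.24 (adjusted p = 0.0344), with means of -0.16 ± 0.60 and 1.02 ± 0.50 and all 6 GnRHa arrays below the control mean. It stayed past the threshold in 6 of 11 fits that left out 1 array. TYROBP, a signalling adaptor of microglia, stood at 0.45 ± 0.11 (adjusted p = 0.0567) and the leptin receptor LEPR at -1.32 ± 0.33 (adjusted p = 0.0598). On the right CHIA, a chitinase, had a fitted difference of 2.98 ± 0.61 (adjusted p = 0.162), with means of 0.77 ± 1.90 in 4 GnRHa and -0.59 ± 0.64 in 3 control arrays and a range of 0.24 to 4.30 over the settings. EDNRB stood at -0.97 ± 0.27 (adjusted p = 0.362) and the myoglobin gene MB at 2.42 ± 0.71 (adjusted p = 0.387). The difference between the sides in males passed for 26 probes (11 higher and 15 lower on the right), with LMNB1, a nuclear lamin, at 4.61 ± 0.93 (adjusted p = 0.0352; past the threshold in 9 of 21 fits that left out 1 array, and 1.92 to 5.17 over the settings). CHIA stood there at 4.26 ± 0.95 (adjusted p = 0.0917; -0.05 to 6.29 over the settings) and ISL1 at -4.22 ± 0.97 (adjusted p = 0.111). The left count was 6 without male GnRHa left replicate 6 and 90 without male control left replicate 5, the right count 9 without male control right replicate 5, and the count of the difference 80 without that last array. Left, right and difference counts were 39, 0 and 5 with the twin pair as a fixed replicate block, 0, 0 and 11 with the compared groups alone in the fit, and 0 each with all 56 columns.

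In the female left and right amygdala limma called 0 probes for the GnRHa effect, with 627 and 810 at an unadjusted p under 0.05. With all 56 columns as planned it also called 0 on each side. On the left the oxytocin receptor OXTR stood at 2.08 ± 0.64, PYGL at -0.70 ± 0.21 and the glutathione transferase GSTA1-1 at 1.15 ± 0.42 (adjusted p = 0.990 for each). On the right HRH2 stood at 0.45 ± 0.13 (adjusted p = 0.420), CD86, a co-stimulatory receptor of antigen-presenting cells, at 0.97 ± 0.30 (adjusted p = 0.537) and the oxidase NOX5 at 0.37 ± 0.12 (adjusted p = 0.555). The difference between the sides passed for 1 unnamed probe. CCR3 stood there at 2.28 ± 0.63 (adjusted p = 0.401), PTGER3 at -1.77 ± 0.52 and NOX5 at 0.54 ± 0.16 (adjusted p = 0.411 for both). The right count was 20 without female GnRHa right replicate 5 and 146 with array weights. The 1 probe of the difference was not called with the twin pair as a replicate block, without a dye term or with all 56 columns. Its count fell to 0 in 16 of the 20 fits that left out 1 array.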

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

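The 3 patterns weighed here were picked after the counts were seen, and of their tests those of the microglia list, of the far-out arrays, of the left-out males and of the splits without the 2 sex-parting probes were chosen after results that bear on them were seen. In the values per array of 35 named genes, 231 groups of 4 to 6 arrays were searched for an array far from the others, and 17 were found where 11.55 would come by chance.

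TRPM7 had 3 such arrays: male control left replicate 5 at 1.89 (others 0.72 to 0.97), male GnRHa left replicate 6 at -1.32 (others -0.17 to 0.35) and male GnRHa right replicate 2 at 0.29 (others -0.67 to -0.40). CXCL1 stood at 0.88 in female control right replicate 4 (others -0.46 to -0.27) and PYGL at -1.26 in female GnRHa right replicate 3 (others -0.37 to -0.09). Male GnRHa left replicate 2 stood apart for TNFSF13B at -0.24 (others -1.69 to -1.40) and for CAPN3 at 0.85 (others -0.12 to 0.14). Male GnRHa right replicate 7 did so for TM7SF2 at 0.28 (others -0.24 to -0.05) and for TGFB2 at -0.72 (others -0.39 to -0.22). Female GnRHa left replicate 5 did so for RPS6 at -0.41 (others -0.07 to 0.07) and for the aromatase gene CYP19 at -2.29 (others -0.62 to -0.37). ATXN2L stood at 0.78 in male GnRHa left replicate 5 (others -0.30 to -0.21), CTSS at 1.20 in female control left replicate 4 (others -0.59 to -0.25) and MTHFD2 at -2.17 in female GnRHa left replicate 3 (others 0.01 to 0.72). TNNC2 stood at 1.04 in male control right replicate 2 (others 0.45 to 0.50), PADI3 at 1.57 in female GnRHa right replicate 4 (others 0.32 to 0.52) and ARNT2 at -2.09 in female control left replicate 5 (others -0.14 to 0.41).

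Differences between groups in the same contrast were found by their own test. The GnRHa effect differed between the sides at 26 probes in males and at 1 probe in females. The sex difference differed between the sides at 136 probes in untreated animals (35 higher and 101 lower on the right) and at 689 in GnRHa-treated animals (357 and 332). The counts of the sex difference come from the main fit alone, without the alternatives and the splits. As fitted, all left female arrays carried Cy3 and all right ones Cy5. Of the male GnRHa arrays 2 of 6 carried Cy5 on the left and 4 of 6 on the right. Both counts therefore lean on the dye term, and in females side and dye cannot be told apart. The GnRHa effect on ribosomal protein genes differed between the sexes with an adjusted p of 0.0293 with the preset correlation and 0.809 with an estimated correlation. Exchanges within twin pairs allow 16 splits in males and 8 in females, too few for a share under 0.05. For the 26 probes in males 1 of 16 gave as many (highest other 4), and for the 1 probe in females 1 of 8 (highest other 0).

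The first pattern is that more probes differed by sex in the untreated left amygdala (661) than in the untreated right (10). Each count taken alone had a share of splits under 0.05. On the left 1 of 100 splits, the real one, gave as many (highest other 479), and on the right 1 of 100 (highest other 2). The same holds without the 2 sex-parting probes FE028749 and CU655072, with p-values adjusted again. The counts were then 659 (1 of 100, highest other 478) and 8 (1 of 100, highest other 2). The left count was not set against the right in the splits. Of the other splits 17 called probes on the left. Those with 479, 466 and 461 there called 0 on the right, so the splits do not exclude chance for the contrast between the sides. The median standard error on the left was 0.956 times that on the right. The fit shares 1 spread per probe over all groups. The ratio therefore reflects numbers of values and dyes, and cannot show whether the left arrays spread less. Dye and side cannot be told apart, since as fitted all control right arrays carried Cy5 and all but 1 control left array Cy3. Cy3 arrays alone (median difference of the called probes 0.804, against 0.783 in all arrays) therefore leave out 1 array. The arrays far out on the first principal component cannot be told apart from other arrays as the source of the calls: without the 2 in female control left the counts were 22 on the left and 24 on the right, and without another pair of that group 6 to 1297 on the left. Also open are that single arrays set the count, which was 128 without male control left replicate 3, and that sex acts differently on the sides (136 probes passed the test of the difference itself).

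The second pattern is that interferon-induced genes had positive differences in GnRHa-treated females against GnRHa-treated males, with a mean log2 difference of 0.861 over ISG15, which alone passed the threshold, IRF1, MX1 and MX2. Leaving out 1 GnRHa female at a time gave means of 0.614 to 1.07, and 1 GnRHa male at a time 0.728 to 0.97. No single animal made the mean difference, although ISG15 stayed past the threshold in 5 of 22 fits without 1 array. Not every GnRHa female was raised. The means of these genes per array were -0.36 and -0.65 in female replicate 3 and -0.62 and -0.38 in replicate 7. GnRHa male arrays ran from -1.70 to 0.30. Female replicates 4, 5 and 6 ran from 0.33 to 2.29. The mean of 0.861 includes ISG15 itself (1.70). Blood cells in the tissue cannot be told apart from a response of the tissue because the list has 2 measured genes, although their mean difference was -0.600 (AHSP -1.19, HBB -0.01). More microglia and macrophages also cannot be told apart, since the 6 genes of that list had a mean difference of 0.188 with a standard error of 0.239 and went both ways (CTSS 0.98, ITGAM -0.74). An effect of the agonist itself that differs by sex is open too, and the interaction of ISG15 was 0.63 ± 0.55 (adjusted p = 0.824). Such an effect cannot be told apart from the length of treatment, since males began at 8 weeks and females at 28.

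The third pattern is the set of 29 probes that differed between right and left. Of 100 splits 2 gave as many, the real one included. The splits exchanged sides but not dyes, while side and dye coincide in females as fitted, so they cannot exclude chance. The highest other split, which exchanged the sides of 8 of 16 animals, gave 472, which points to a structure of the arrays whose source was not tested. In males alone, with the dye term, the 29 probes kept their direction with a median of 1.47 against 2.12 in all animals. The dye term of the full fit rests on male arrays too, since each female group held 1 dye as fitted. The male fit therefore largely repeats the fit that chose the probes. In females alone, without a dye term, the median was 0.349. Side and dye cannot be told apart because they coincide in females as fitted, and 23 of the 29 had the fitted direction in plain means of all arrays and 16 in plain means of male arrays. Of the 29 probes, 65.5% lay in the dimmest 25% of the tested probes, so noise near background remains a candidate explanation, and a difference between the sides is open as well.

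For the other counts, the share of splits was under 0.05 for the sex difference in untreated animals (134 probes, 3 of 100 splits, highest other 203). It was also under 0.05 in GnRHa-treated animals (20, 1 of 100, highest other 1). The same holds in the treated left amygdala (285, 1 of 100, highest other 2) and in the treated right (4, 1 of 100, highest other 1). These shares were not adjusted over the counts tested. Other splits gave 203 and 135 calls in untreated animals, so permuted labels can reach that count. Without the 2 sex-parting probes, and with p-values adjusted again over the others, the share stayed under 0.05 for each. The counts were then 131 in untreated animals (3 of 100, highest other 203) and 15 in treated animals (1 of 100, highest other 1). They were 283 on the treated left (1 of 100, highest other 2) and 2 on the treated right (1 of 100, highest other 1). The splits are too few for the GnRHa effect in the male left (39; 2 of 16, highest other 66) and right amygdala (4; 1 of 16, highest other 0). A count of 0 is reached by every split, as for the GnRHa effect in males (1519 probes at an unadjusted p under 0.05 in limma; 16 of 16, highest other 140), in females (480; 8 of 8, highest other 3), in the female left (627; 8 of 8, highest other 0) and right amygdala (810; 8 of 8, highest other 0) and for the sex by GnRHa interaction (996; 78 of 78, highest other 10). The male split with 140 calls, which changed the label of 4 of 13 males, points to a structure of the arrays whose source was not tested. All treatment splits part the 10 complete twin pairs, as the real split does. For gene lists the splits are too few for GnRHa in males (1 list; 5 of 16, highest other 2) and in females (0; 8 of 8, highest other 4). Chance cannot be excluded for lists in the interaction (1; 22 of 78, highest other 3), the sex difference untreated (0; 100 of 100, highest other 6) and treated (3; 6 of 100, highest other 4) and right against left (1; 11 of 100, highest other 3).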

How the results depend on the processing

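The tests on the 41 arrays as deposited, on all 56 columns, without or with relabelled turned arrays, on probes measured on every array, on a common scale, without each array in turn and without the 4 far-out arrays were chosen after the data were seen. The counts compared are 0 for GnRHa in males, 0 for GnRHa in females, 134 for sex untreated, 20 for sex treated, 0 for the sex by GnRHa interaction, 29 for right against left, 39 for male left, 4 for male right, 0 for female left, 0 for female right, 661 for untreated left, 10 for untreated right, 285 for treated left, 4 for treated right, 26 for GnRHa by side in males, 1 for GnRHa by side in females and 6 gene lists. Only counts that moved by more than 1.5 times are given, and the cause was not tested except where fewer arrays or probes were in the fit. The interaction of sex and GnRHa and the female left amygdala stayed at 0 in limma under every alternative run, with 996 and 627 probes at an unadjusted p under 0.05. Of 82 values of named genes, under 16 other settings and each array left out, 2574 stayed on their side of the threshold (called ones in their direction, others within 1 SD), 280 lost it, 69 gained it and 30 that were not called moved by over 1 SD. Most of the 82 were not called in the main fit and could not lose the threshold, so the 2574 do not give the stability of the called genes. With the mean of all probes of a gene, 8 of the 82 lost the threshold and 1 gained it. Another 7 that were not called moved by over 1 SD. In the treated sex difference ISG15 kept its call 15 times and lost it 22 times, and CTSS kept it 33 times and lost it 4 times. Values not called turned sign 50 times, in 11 of the 82. Of the called values 1 reversed, PADI3 in right against left, at 0.45 (adjusted p = 0.632) without a dye term, where its range over the settings was -3.22 to 0.45 and its adjusted p 0.0240 to 0.807. The dim end limits the signal: probes missing from some arrays are the dim ones, and the ratios hold no background values. Background correction, normalization within or between arrays and the slide were not run, and the deposited values are themselves the input.

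Without the dimmest 25% of the probes the counts were 12 for GnRHa in males, 12 for right against left, 2 for male right, 7 for treated right and 3 for GnRHa by side in males. Without a dye term the counts were 557 for right against left, 15 for male left, 0 for male right, 7 for treated right, 0 for GnRHa by side in males, 0 for GnRHa by side in females. Without the animal block the counts were 54 for GnRHa in males, 246 for sex untreated, 48 for sex treated, 9 for right against left, 4 for GnRHa by side in males and 0 for GnRHa by side in females. With the twin pair as the random block the counts were 62 for GnRHa in males, 1 for GnRHa in females, 36 for sex treated, 62 for male left, 4 for GnRHa by side in males and 0 for GnRHa by side in females. With the twin pair as a fixed replicate block the counts were 11 for right against left, 0 for male right, 5 for GnRHa by side in males and 0 for GnRHa by side in females. With array weights the counts were 178 for GnRHa in males, 3 for GnRHa in females, 276 for sex untreated, 139 for sex treated, 91 for right against left, 89 for male left, 146 for female right, 402 for untreated left, 181 for untreated right, 2556 for treated left, 59 for treated right, 54 for GnRHa by side in males and 64 for GnRHa by side in females. With a trended and robust variance prior the counts were 12 for GnRHa in males, 49 for sex treated, 23 for untreated right, 436 for treated left, 19 for treated right and 0 for GnRHa by side in females. With the compared groups alone in the fit the counts were 2 for sex untreated, 0 for male left, 0 for male right, 3 for untreated left, 1 for untreated right, 8 for treated left, 11 for GnRHa by side in males and 0 for GnRHa by side in females. Gene list calls were 2 without a dye term, 0 with the estimated correlation, 0 with fry (which could test 5 of the 6) and 1 with the twin pair as a fixed replicate block within a sex.

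With all 56 columns as deposited the counts were 2 for sex untreated, 3 for sex treated, 0 for right against left, 0 for male left, 0 for male right, 3 for untreated left, 0 for untreated right, 8 for treated left, 0 for treated right, 0 for GnRHa by side in males, 0 for GnRHa by side in females and 0 for gene lists. With the 41 arrays as deposited the counts were 71 for sex untreated, 7 for sex treated, 3 for right against left, 0 for male left, 0 for male right, 0 for untreated right, 4 for treated left, 0 for treated right, 1 for GnRHa by side in males, 0 for GnRHa by side in females and 2 for gene lists. Without the 3 turned arrays the counts were 77 for sex untreated, 4 for sex treated, 18 for right against left, 4 for male left, 2 for male right, 6 for untreated right, 13 for treated left, 3 for GnRHa by side in males and 0 for GnRHa by side in females. With the 3 arrays turned and their dye as labelled the counts were 17 for GnRHa in males, 3 for right against left, 17 for male left, 72 for treated left, 3 for GnRHa by side in males, 0 for GnRHa by side in females and 3 for gene lists. With probes measured on every array the counts were 19 for GnRHa in males, 242 for sex untreated, 46 for sex treated, 0 for right against left, 2 for male right, 21 for treated right and 0 for GnRHa by side in males. On a common scale between arrays the counts were 8 for GnRHa in males, 28 for sex untreated, 50 for sex treated, 46 for right against left, 4 for female right, 181 for untreated left, 447 for treated left and 55 for treated right. Without the 4 arrays far out on the first component the counts were 13 for sex untreated, 4 for sex treated, 15 for right against left, 1 for male right, 25 for untreated left, 17 for treated left, 2 for GnRHa by side in males, 0 for GnRHa by side in females and 2 for gene lists.

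With each array left out in turn the counts ran from 0 to 136 for GnRHa in males, 0 to 3 for GnRHa in females, 7 to 349 for sex untreated, 4 to 66 for sex treated, 3 to 58 for right against left, 6 to 90 for male left, 1 to 9 for male right, 0 to 20 for female right, 128 to 921 for untreated left, 3 to 52 for untreated right, 16 to 582 for treated left, 3 to 22 for treated right, 4 to 80 for GnRHa by side in males and 0 to 8 for GnRHa by side in females. For sex untreated 14 of the 19 arrays moved the count by over 1.5 times, for sex treated 16 of 22, for untreated left 4 of 10 and for treated left all 11. The lowest counts were reached without male control right replicate 3 (sex untreated), male GnRHa left replicate 1 (sex treated), male control left replicate 3 (untreated left) and female GnRHa left replicate 6 (treated left), and the highest for GnRHa in males without male control right replicate 5. Where several arrays tied for such a count, only the first of them is named.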

Other observations

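The tests of pairing and the sums over lists below were chosen after the data were seen. Lists too small to test as a set held few named genes, given here as values of limma's fit. In untreated animals FLT1, a VEGF receptor of endothelium, stood at -0.96 ± 0.36 in females against males (adjusted p = 0.172) and the serotonin receptor HTR2A at -0.57 ± 0.32 (adjusted p = 0.416). UBA1, the measured X-linked gene with a Y partner, stood at 0.29 ± 0.15 (adjusted p = 0.342) and TF, an iron carrier of oligodendrocytes, at 0.36 ± 0.26 (adjusted p = 0.561). The proliferation gene PCNA stood at -0.31 ± 0.14 (adjusted p = 0.272). In right against left the noradrenaline transporter SLC6A2 stood at 1.69 ± 0.50 (adjusted p = 0.155). The striatal gene ISL1 stood at -1.79 ± 0.56 for GnRHa in females (adjusted p = 0.963). The choroid plexus genes AQP1 and TTR stood at 1.12 ± 0.59 (adjusted p = 0.477) and 0.31 ± 0.74 (adjusted p = 0.921) for GnRHa in males. The respiratory chain gene ATP5MC2 stood there at 0.04 ± 0.08, and the cholesterol gene SQLE at 0.05 ± 0.14. Immediate early genes gave a list adjusted p of 0.981 in that comparison, with JUN at -0.17 ± 0.09. The lists of GABA neurotransmission, Y-linked genes, neurons, and hippocampus and cortex had 0 tested members.

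Among unnamed probes that the named genes do not cover, EE780318 was higher in treated females than in treated males by 1.12 ± 0.18 (adjusted p = 0.00106), and EE831898 was higher in untreated females than in untreated males by 0.94 ± 0.17 (adjusted p = 0.0145).

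Both sides of 1 animal had a mean correlation of 0.134 over 9370 probes after group means were removed (16 animals), twins on the same side 0.0503 (14 pairs) and unrelated arrays of other groups -0.00366. The correlations are across genes, which are not independent replicates. The first 3 principal components held 12.6, 10.2 and 6.97% of the variance, and 4 arrays stood far out on the first: male GnRHa right replicate 7, female GnRHa left replicate 6 and female control left replicates 3 and 6.

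In the authors' tables of each group against the pool, the number of probes with an adjusted p below 0.05 was 875 for female GnRHa left, 68 for female GnRHa right, 73 for female control left, 97 for male control left and 0 for each of the other 4 groups. In the 15 columns left out, probes without a value had a mean log2 brightness of 6.07 to 6.18 and probes with one 6.22 to 6.26.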
